A study of Homo sapiens with 6 samples.

How the data were processed

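RNA was measured in 6 cultures of the glioblastoma line U87, 3 infected with a retroviral scramble vector (shCTR) and 3 with a retroviral vector that silences Caspase-8 (shC8). Per the labels' protocols, total RNA was treated with DNase, depleted of ribosomal RNA and made into stranded libraries. The series' design text calls the 3 samples of each group biological replicates, and it does not say how the cultures or infections were separated, so p-values measure the spread between these samples. The sequence and number of hairpins were not given in the sources used here.

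The table holds FPKM per gene symbol and library as the authors deposited it. TopHat, Cufflinks and Cuffdiff and the genome build hg38 are named in the submitters' processing notes, without versions or roles. The annotation, the use of strand in counting and any further scaling between libraries were not given in the sources used here. FPKM divides by gene length and by a library total, so a large change in a few abundant genes shifts all others, and reads of near-identical genes can be split by the estimator. Values listed at 0 can be failed estimates, and ANKRD28 is an example, at 17.7 and 22.8 FPKM in shCTR 1 and 3 and listed at 0 in the other 4 libraries. For genes listed at 0 in a whole group, each library's value is given and no fold. Every sample column of the table was used.

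FPKM values carry no counts, so no count model was run and no counting interval is given. Absolute depth is unknown. Among genes under 0.05 FPKM, the most common ratio to shCTR 1 gave relative depths of 1.2 and 1.09 for shCTR 2 and 3 and of 1.09, 1.12 and 1.15 for shC8 1, 2 and 3. The columns summed to between 489055 and 516634 FPKM.

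Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma's moderated test with a mean trend, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes with low values. Folds written as "-fold" are ratios of mean FPKM. The exact permutation test was used for CASP8 alone. The 41 gene lists were fixed before the data were examined, as were the main tests and most alternatives. Lists with at least 5 tested members, 37 of them, were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, and p-values were adjusted over the lists. For each list, members that passed were counted after adjustment over all genes and after adjustment over the list alone. List symbols absent from the table were matched through older symbols in a RefSeq gene table.

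The genes named in the text follow a rule written before the data were examined. It takes CASP8, RELA, NFKB1, SRC, VEGFA, IL6, CXCL8 (IL8 in the table) and CCL2 whatever their values, then the 12 largest rises and 12 largest falls that passed with groups that did not overlap. For each list called by camera and for the NF-kB target, cytokine, angiogenesis, death receptor and DNA repair lists, it takes up to 4 passing members with the largest changes. From lists of other cell types or RNA quality it takes the 3 tested members of highest FPKM. Every other gene named in the report or after it, such as those named beside a count of 5 or fewer, was chosen after its values were seen. Some genes that the rule or a count would name are not reported here.

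Replicate numbers 1 to 3 occur in both groups. Deviations from the group means correlated across genes between same-numbered libraries at 0.397, 0.266 and 0.291, all over 0.1, so the numbers were taken to pair the samples, from the data and not from a label that says so. The fit without a block stays the main one, as fixed beforehand, and blocked values stand beside results whose call or count they change.

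Alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, quantile normalization, median-of-ratios scaling, the replicate block, moderation without a trend, a log2 threshold of 1, and each library left out in turn. A term for the range of the column numbers, and a fit without genes whose 3' UTR holds GGACAAA, were added after seeing the data. The longest annotated 3' UTR of each gene (at least 50 bases, GENCODE 29, build GRCh38, which is the assembly called hg38) was searched for every word of 7 bases found in at least 50 genes. For each word, fold changes (limited to ±2) adjusted for 3' UTR length and GC content were compared between genes with and without the word as a z score, beside 100 random reassignments of fold changes to genes. A 3' UTR was found for 10819 of 11598 tested genes (93.3%).

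Scripts were tested on simulated data. With 200 of 11598 genes changed in a simulated comparison of shC8 against shCTR, limma recovered 54% of 100 genes changed by 0.5 and 87% of 100 genes changed by 1 on the log2 scale, and 3.42% of the calls were false. A planted word with a shift of -0.15 among 10819 genes came out with the lowest z. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.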

Results

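RNA from U87 cells, an established human glioblastoma line, was sequenced after retroviral infection with a scramble control (shCTR, 3 libraries) or for silencing of Caspase-8 (shC8, 3 libraries). Caspase-8 is the initiator protease of death receptor signalling. The study's title concerns SRC kinase, NF-kB activity, angiogenesis and resistance to therapy in glioblastoma, so genes of these processes were read first. The deposited table gave 1 FPKM value per gene and library (fragments scaled by transcript length and by mapped fragments in the library) for 23290 genes, of which 4566 were listed at 0 in every library. Between 16326 and 17024 genes had a value above 0 in a library. Absolute depth was unknown, and steps among the lowest values placed the depth of the other 5 libraries between 1.09 and 1.2 times that of shCTR 1. Correlations of log2(FPKM + 1) across the 11598 tested genes lay between 0.984 and 0.988 within groups and between 0.968 and 0.981 between groups. These are correlations across genes, which are not independent replicates.

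CASP8 (ENSG00000064012), on the plus strand of chromosome 2 from 201233443 to 201287711 of the GRCh38 build, was lower in every library labelled shC8. Its FPKM was 15.1, 14.9 and 13.4 in shCTR 1, 2 and 3, and 4.39, 4.46 and 4.44 in shC8 1, 2 and 3. The means were 14.5 ± 0.937 and 4.43 ± 0.0353 FPKM (SD, n = 3 each), so 30.6% of the control level was left. On the log2(FPKM + 1) scale the change was -1.51 (SE 0.0705, limma adjusted p = 0.000206). An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest value this design allows. Numbers in the deposited column names fall into a lower range (shCTR 1, shCTR 3 and shC8 1) and an upper range (shCTR 2, shC8 2 and shC8 3), whose meaning was not stated. Within the lower range the CASP8 change was -1.50 and within the upper range it was -1.55.

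**Figure D1:**
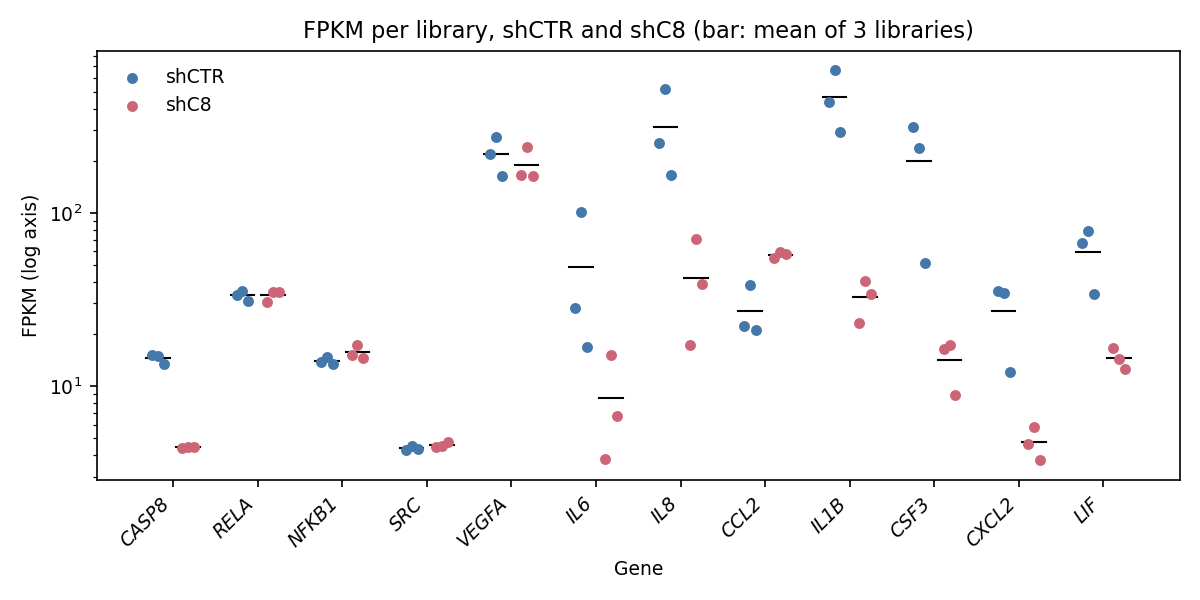
FPKM on a log axis for the 8 genes chosen before the data were examined and for 4 cytokine genes that fell, with 1 point per library and a bar at the mean of 3 libraries of each group (shCTR blue, shC8 red). CASP8 lay between 4.39 and 4.46 in shC8 against 13.4 to 15.1 in shCTR, while the points of RELA overlapped between the groups.

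The largest falls in shC8 included the cytokine genes IL1B and CSF3, and the largest rises included the surface glycoprotein gene CD24 and the protease inhibitor gene TIMP3. Of the 11598 genes tested, 828 were higher and 573 lower in shC8 (limma, adjusted p under 0.05), so 59.1% of the 1401 calls were higher. With median-of-ratios scaling of the columns the higher share of 1441 calls was 43.1%, while the median change of all genes moved from 0.0376 to -0.00752. All 1401 genes changed in the same direction in each of the 3 pairs of same-numbered libraries, which their selection from these same libraries largely implies. Changes of at least 1 on the log2 scale were seen for 96 of them, 46 higher and 50 lower. The 2 groups did not overlap for 4034 genes, 34.8% of those tested, where chance gives 10%. With the replicate number as a block, 3086 genes were called, 1862 higher and 1224 lower, and they included all 1401. The count depended on single libraries: it was 642 without shCTR 1, 644 without shCTR 2, 840 without shCTR 3, 574 without shC8 2 and 477 without shC8 3.

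Of the 8 genes fixed as a panel, CASP8 and IL8 fell, CCL2 rose and 5 did not pass the test. RELA and NFKB1, which encode NF-kB subunits, had log2 changes of 0.00 (SE 0.0788, adjusted p = 0.994) and 0.15 (SE 0.0815, adjusted p = 0.266). For SRC the change was 0.05 (SE 0.0703, adjusted p = 0.65), and for VEGFA, the main vascular growth factor, it was -0.20 (SE 0.21, adjusted p = 0.555). Over the alternatives VEGFA lay between -0.395 and -0.0302 and never passed. IL6 averaged 49 ± 46 FPKM in shCTR and 8.54 ± 5.88 in shC8 (SD, n = 3 each), a change of -2.17 with a limma adjusted p of 0.0748. Without shCTR 2 the change of IL6 was -1.44 (limma adjusted p = 0.133). With the replicate block the adjusted p of IL6 was 0.00548, and with the column number range as a term it was 0.00799. The chemokine gene CCL2 rose from 27.2 ± 9.6 to 57.4 ± 2.49 FPKM (SD, n = 3 each), by 1.10 (SE 0.203, limma adjusted p = 0.0164). Its adjusted p reached between 0.0571 and 0.0634 when shCTR 1, shC8 2 or shC8 3 was left out.

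Several cytokine genes that NF-kB is known to activate fell, and CCL2 rose. IL1B, which encodes the inflammatory cytokine interleukin-1 beta (minus strand of chromosome 2, 112829751 to 112836903), dropped from 464 ± 187 to 32.6 ± 8.81 FPKM (SD, n = 3 each), 14.3-fold lower, with a log2 change of -3.75 (SE 0.305, limma adjusted p = 0.00132). CSF3, the granulocyte growth factor gene (chromosome 17, 40015361 to 40017813), was 14.1-fold lower. IL8, a neutrophil chemokine gene now named CXCL8 (chromosome 4, 73740506 to 73743716), was 7.41-fold lower, CXCL2 5.78-fold and LIF 4.11-fold. Of 33 tested NF-kB target genes, 10 fell, 1 rose (CCL2) and 22 did not pass, with 13 falls and 1 rise adjusted over the list alone and 16 falls with the replicate block. The list's median log2 change was -0.41 (camera adjusted p = 0.000113 with the preset correlation, adjusted p = 0.826 with an estimated correlation). Of 23 cytokine and chemokine genes, 8 fell, 2 rose (CCL2 and IL18) and 13 did not pass, with 12 falls and 3 rises adjusted over the list alone and 13 falls with the replicate block. Their median was -0.59 (camera adjusted p = 0.000495, adjusted p = 0.826 with an estimated correlation), and it was -0.28 without a filter on low values, -2.03 with a minimum mean of 5 FPKM and -0.39 without shC8 3. Under quantile normalization and under median-of-ratios scaling 9 cytokine genes fell and 1 rose. Without shCTR 3 the median of the NF-kB targets was -0.64. These lists share 12 tested genes, so they are not separate evidence. Within the lower and upper ranges of column numbers, the medians were -0.22 and -0.60 for the NF-kB targets and -0.41 and -0.86 for the cytokines. Both medians were negative in all 3 pairs of same-numbered libraries, with sizes of at least 0.126 and 0.475, while libraries of 1 group differed from each other by up to 0.648 and 0.838. Leaving out 1 library ended the calls of CSF3 (shCTR 2 or shC8 3, adjusted p up to 0.0652), IL8 (shCTR 1 or shC8 3, up to 0.0634) and CXCL2 (shC8 3, 0.0582). Calls of other counted members ended as well. Of the 6 fits without 1 library, CXCL1, CXCL3 and IL18 kept their call in 1 and CFLAR in 0, while IL1B and LIF kept theirs in 6.

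Among 25 tested components of the NF-kB pathway itself, 4 rose and none fell over all genes and adjusted over the list alone: IKBKG by 0.29, RBCK1 by 0.40, TNFRSF1A by 0.51 and TRADD by 0.52 on the log2 scale (camera adjusted p = 0.272 for the list, and 3 rises under each scaling). These 4 were named after their values were seen. Of the 6 fits without 1 library, TRADD kept its call in 6, TNFRSF1A in 5, IKBKG in 1 and RBCK1 in 0.

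Besides cytokines, the 12 largest falls held matrix proteases, an epidermal growth factor receptor ligand and protease inhibitors. EREG, which encodes the ligand epiregulin (chromosome 4, 74365143 to 74388751), went from 392 ± 19.3 to 74.7 ± 4.35 FPKM (SD, n = 3 each), a log2 change of -2.38 (SE 0.0722, limma adjusted p = 2.57e-05). SERPINB2, an inhibitor of plasminogen activators, was 7.32-fold lower, the stromelysin gene MMP3 8.09-fold and the collagenase gene MMP1 3.91-fold. The transporter gene SLC16A6 was 8.77-fold lower, PI3, an elastase inhibitor gene, 6.16-fold, and PTGS2, which encodes the prostaglandin enzyme COX-2, 4.32-fold. PI3 stood at 0.931, 2.51 and 0.426 FPKM in shC8 1, 2 and 3, so its fold rests on low values that differ between libraries. The calls of PI3 and PTGS2 ended without shCTR 1, shCTR 2, shC8 1 or shC8 3, with adjusted p up to 0.0817 and 0.0894.

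**Figure D2:**
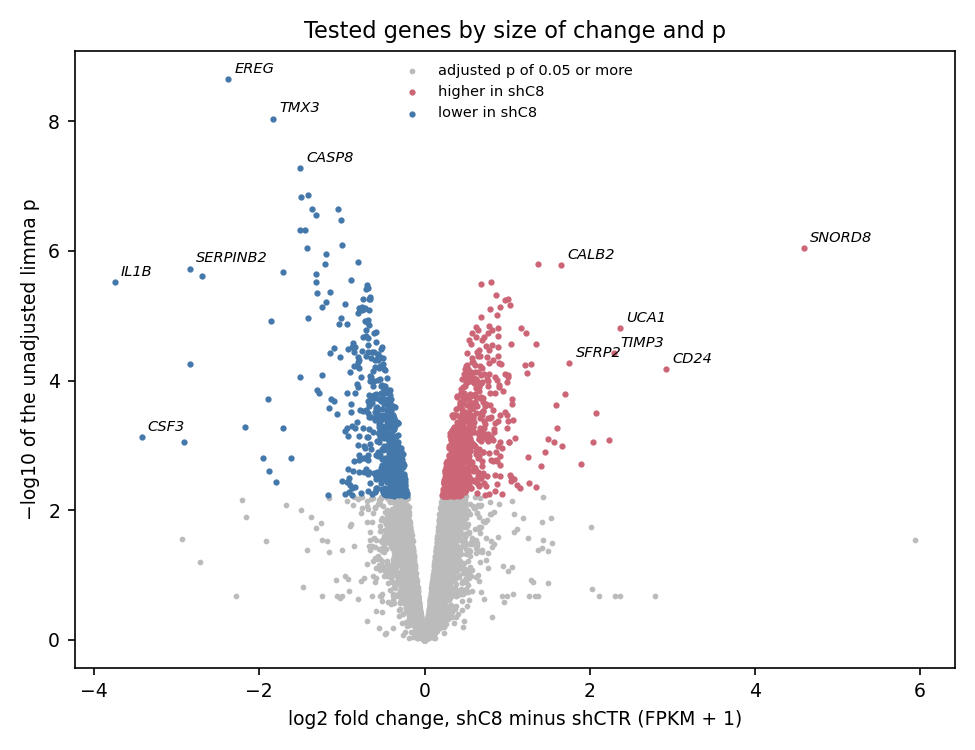
Log2 fold change (shC8 minus shCTR, on FPKM + 1) of the 11598 tested genes on the horizontal axis against −log10 of the unadjusted limma p on the vertical axis, with genes at an adjusted p under 0.05 in red (828 higher) and blue (573 lower). EREG has the highest point among the falls, and SNORD8, listed at 0 in every shCTR library, stands at the right, where its position depends on the pseudocount.

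Some genes of the MAPK feedback and immediate early list fell. DUSP6, a phosphatase gene that ERK signalling induces, dropped from 76.6 ± 14.5 to 35.3 ± 5.9 FPKM (SD, n = 3 each), with a log2 change of -1.09 (SE 0.163, limma adjusted p = 0.00873). CCND1, the cyclin D1 gene, changed by -0.71, the AP-1 gene FOSL1 by -0.67 and the phosphatase gene DUSP4 by -0.66. Of 26 tested members, 6 fell, 1 rose (JUNB, by 0.35) and 19 did not pass, with 13 falls adjusted over the list alone and 14 with the replicate block. The list's median was -0.29 (camera adjusted p = 2.95e-05, adjusted p = 0.675 with an estimated correlation). It was -0.26 within the lower and -0.35 within the upper range of column numbers, beyond the largest difference of 0.11 between libraries of 1 group. The 3' UTR of FOSL1 holds the word GGACAAA, which was found in 33.8% of fallen and 7.3% of risen genes searched, ID4 and HIST2H2BF among the risen. DUSP4 lost its call without shCTR 2 or shC8 3 (adjusted p up to 0.0603).

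The 12 largest rises came from genes of unlike function. CD24, a gene for a surface glycoprotein, rose from 12.5 ± 5.85 to 98.9 ± 38 FPKM (SD, n = 3 each), by 2.93 (SE 0.369, limma adjusted p = 0.00498), and it has near-identical copies that could share its reads. TIMP3, a metalloprotease inhibitor gene (chromosome 22, 32801701 to 32863043), rose from 28 ± 6.89 to 143 ± 45.2 FPKM, by 2.29 (SE 0.265, limma adjusted p = 0.0039). The long noncoding RNA UCA1 was at 0.0827, 0.0165 and 0.207 FPKM in shCTR and at 2.82, 5.16 and 6.78 FPKM in shC8. SNORD8, a small nucleolar RNA, was listed at 0 in all 3 shCTR libraries and at 23.7, 13.4 and 38.4 FPKM in shC8, for which no fold is given. Among 104 tested small RNA genes, 51% were listed at 0 in at least 1 library, against 3 of 11494 other genes. The other rises were CALCB (2.24), SERINC2 (2.07), CPA4 (2.04), BAMBI (1.89), the Wnt-binding protein gene SFRP2 (1.76), MEST (1.71), the retinoic acid binding protein gene CRABP2 (1.67) and the calretinin gene CALB2 (1.65). CALCB stood at 0, 0.237 and 0.81 FPKM in shCTR 1, 2 and 3 and at 2.43, 5 and 10.4 in shC8 1, 2 and 3. The size of its change therefore depends on the pseudocount. Leaving out 1 library ended the calls of CALCB (shCTR 1, shCTR 2 or shC8 2, adjusted p up to 0.0594), CPA4 (shCTR 1, shC8 2 or shC8 3, up to 0.0715), BAMBI (shCTR 1, shCTR 2, shC8 2 or shC8 3, up to 0.0879) and CRABP2 (shC8 2 or shC8 3, up to 0.0749).

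Some antigen presentation genes rose. HLA-B went from 58 ± 8.48 to 113 ± 17.6 FPKM (SD, n = 3 each), by 0.96 on the log2 scale (SE 0.135, limma adjusted p = 0.00751). HLA-F and HLA-C rose by 0.87 and 0.70. These class I genes resemble each other and could share reads. Of 21 tested genes, 8 rose, 1 fell (CIITA, the class II activator gene, by 0.46) and 12 did not pass, with the same counts adjusted over the list alone. The median was 0.17 (camera adjusted p = 0.00351, adjusted p = 0.826 with an estimated correlation), 0.31 within the lower and 0.10 within the upper range of column numbers, at least 0.174 in each of the 3 pairs and 0.27 without shC8 3, while libraries of 1 group differed by up to 0.217. HLA-F lost its call without shCTR 1, shCTR 3, shC8 2 or shC8 3 (adjusted p up to 0.0831). Of 30 interferon-stimulated genes, 6 rose and 3 fell, with 8 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.469). The falls were IFI44L, OASL and IFI44.

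Of 27 proneural and neural progenitor genes only 8 passed the filter on low values, and 6 of these rose. ID3 rose by 1.35, SOX4 by 0.88, ID2 by 0.83 and ID4 by 0.64 on the log2 scale. The ID genes encode inhibitors of helix-loop-helix factors and are known to respond to BMP signalling as well. The median was 0.64 (camera adjusted p = 0.000495, adjusted p = 0.826 with an estimated correlation), with 7 rises adjusted over the list alone, and 0.46 and 0.68 within the lower and upper ranges. Without the filter the median was 0.03 and the list was not called (adjusted p = 0.338, with a range of 3.69e-05 to 0.826 over its alternatives). Libraries of 1 group differed by up to 0.424, under the smallest change of 0.59 in a pair. Only SOX4 among these 4 kept its call in each fit without 1 library. ID3 lost it without any library except shCTR 3 (adjusted p up to 0.129), ID2 likewise (up to 0.0924) and ID4 without any except shC8 1 (up to 0.0994). ID3 also lost its call with the column number range as a term (adjusted p = 0.065). On the mesenchymal list, 5 of 30 genes rose and 3 fell, with 8 and 5 adjusted over the list alone and 12 and 6 with the replicate block (camera adjusted p = 0.421). The falls included FOSL1 and the hyaluronan receptor gene CD44, and with median-of-ratios scaling 5 rose and 5 fell.

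**Figure D3:**
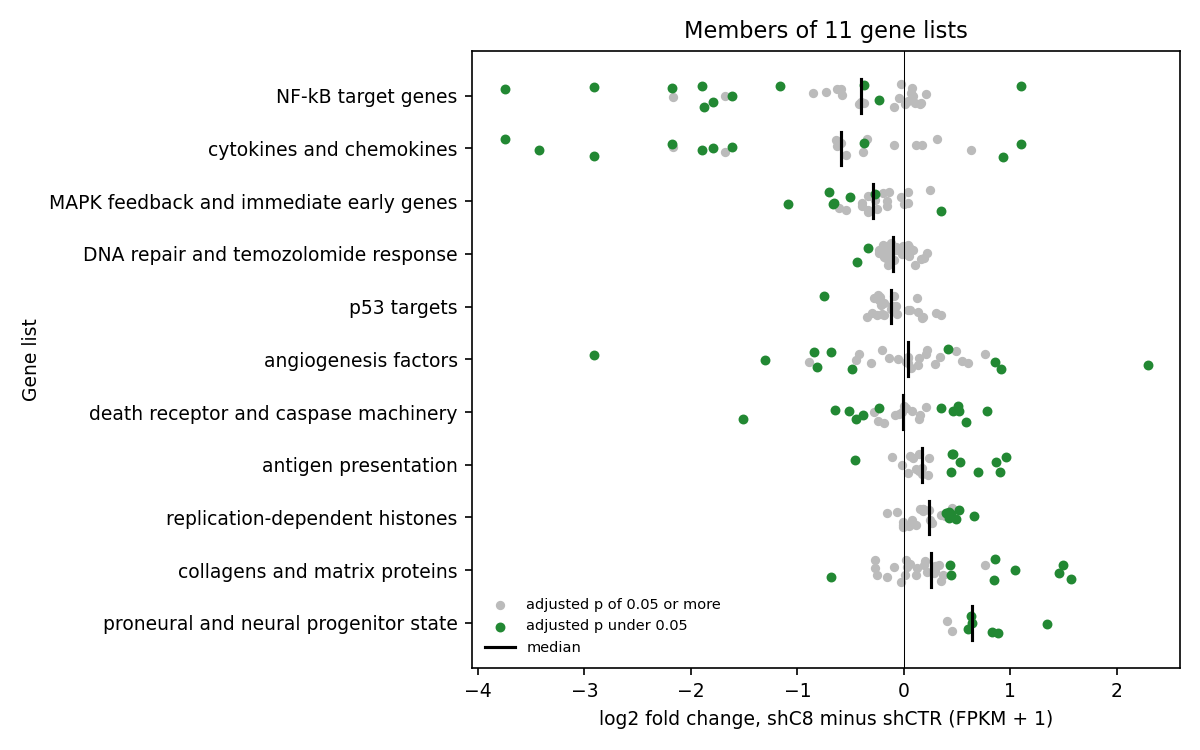
Log2 fold change (shC8 minus shCTR, on FPKM + 1) of each tested member of 11 gene lists, with members at an adjusted p under 0.05 in green, the others in grey and a black line at the list's median. The medians run from -0.59 for cytokines and chemokines to 0.64 for the proneural list, and the angiogenesis list holds members on both sides.

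Angiogenesis factors moved both ways. Besides IL8, the growth factor gene FGF2 fell from 82.5 ± 22.4 to 32 ± 3.38 FPKM (SD, n = 3 each), by 1.31 on the log2 scale (SE 0.184, limma adjusted p = 0.00739). TIMP3 rose, and so did PGF, the placental growth factor gene, by 0.91 (limma adjusted p = 0.0236). Of 32 tested genes, 4 rose, 6 fell and 22 did not pass, with 7 rises and 8 falls adjusted over the list alone and 9 rises and 9 falls with the replicate block (camera adjusted p = 0.533). PGF lost its call without any library except shC8 1 (adjusted p up to 0.081).

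Among genes of collagens and other matrix proteins, called rises outnumbered called falls, while 23 of 32 did not pass. COL1A1 rose from 18.7 ± 3.02 to 56.8 ± 20.7 FPKM (SD, n = 3 each), by 1.49 (SE 0.276, limma adjusted p = 0.0168), and lost its call without shCTR 1, shC8 2 or shC8 3 (adjusted p up to 0.0652). Of 32 tested genes, 8 rose and 1 fell (THBS2), with 9 and 1 adjusted over the list alone and 15 and 1 with the replicate block. The 3' UTRs of COL1A1, COL1A2, COL5A1, COL5A2 and SPARC hold the word TGGTGCT, as do those of the risen ID3, MEST and CALCB and of the fallen EREG and LIF. It was found in 26% of risen and 15.9% of fallen genes searched. The camera adjusted p of the list was 0.0752, which did not pass, and with the replicate block it was 0.00354 (adjusted p = 0.76 with an estimated correlation). Among 25 matrix proteases and inhibitors, 3 rose (MMP2, ADAM19 and TIMP3) and 6 fell, with 6 and 7 adjusted over the list alone and 10 and 10 with the replicate block (camera adjusted p = 0.372). Of 12 integrin genes, 3 rose (ITGA5, ITGAV and ITGA6) and none fell, with 5 and 3 adjusted over the list alone and 5 and 3 with the replicate block (camera adjusted p = 0.331). In the SRC family and focal adhesion list, 2 of 30 rose (VASP and LYN) and 2 fell (LIMS1 and PTK2B), with 3 and 2 adjusted over the list alone and 7 and 4 with the replicate block (camera adjusted p = 0.859). The counts were 1 and 2 under quantile normalization and 2 and 4 under median-of-ratios scaling. Of the 6 fits without 1 library, LIMS1 kept its call in 5 and VASP, LYN and PTK2B in 0. For TGF-beta targets the counts were 4 rises and 2 falls of 24, 5 and 4 adjusted over the list alone and 10 and 6 with the replicate block (camera adjusted p = 0.622). For YAP and TEAD targets they were 1 rise (AXL) and 4 falls (NT5E, DDAH1, ASAP1 and GADD45A) of 22, 2 and 6 adjusted over the list alone and 6 and 7 with the replicate block (camera adjusted p = 0.331), and ASAP1 holds GGACAAA. Of 14 receptor tyrosine kinase genes, 3 rose (INSR, AXL and PDGFRB) and none fell, with 5 and 1 adjusted over the list alone and 5 and 1 with the replicate block (camera adjusted p = 0.331). INSR kept its call in 0, AXL in 3 and PDGFRB in 5 of the 6 fits without 1 library.

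Death receptor and caspase genes changed in both directions. BAK1, which encodes a pore-forming BCL2 family protein, rose from 3.78 ± 0.416 to 7.18 ± 0.375 FPKM (SD, n = 3 each), by 0.78 (SE 0.0889, limma adjusted p = 0.00385). CASP4, an inflammatory caspase gene, fell by 0.64 (SE 0.0861, limma adjusted p = 0.00602). Of 24 tested genes, 6 rose, 6 fell (CASP8 among them) and 12 did not pass, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.559). Of the falls besides CASP8, the decoy receptor gene TNFRSF10D and the inhibitor genes XIAP and CFLAR hold GGACAAA in their 3' UTRs, and they were named after their values were seen. CFLAR changed by -0.23 (limma adjusted p = 0.0402). Of the 6 fits without 1 library, XIAP kept its call in 5, TNFRSF10D in 3 and CFLAR in 0. In the BCL2 family list of 11, BAK1 alone rose and none fell, over all genes and adjusted over the list alone, and 2 fell with the replicate block (camera adjusted p = 0.604).

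Few DNA repair genes passed. OGG1, a glycosylase gene of base excision repair, fell by 0.44 (SE 0.0699, limma adjusted p = 0.0107) and XRCC1, a scaffold gene of the same pathway, by 0.34 (SE 0.0775, limma adjusted p = 0.034). The call of XRCC1 ended without any library except shC8 1 (adjusted p up to 0.0974) and with the column number range as a term (adjusted p = 0.0546). Of 39 tested genes, 2 fell and none rose, with 1 fall adjusted over the list alone and 3 falls and 1 rise with the replicate block. The median was -0.10 (camera adjusted p = 0.0034, adjusted p = 0.826 with an estimated correlation), and -0.06 and -0.10 within the lower and upper ranges. It was negative in all 3 pairs, with a size of at least 0.0559, while libraries of 1 group differed by up to 0.0749. Of 26 p53 targets, ZMAT3 alone fell, by 0.75, over all genes and adjusted over the list alone, while 2 rose and 8 fell with the replicate block, and the 3' UTR of ZMAT3 holds GGACAAA. The median of the p53 list was -0.12 (camera adjusted p = 0.0454, adjusted p = 0.826 with an estimated correlation), and -0.08 and -0.02 within the ranges, -0.07 without shCTR 1 and -0.20 without shCTR 2. It was negative in all 3 pairs, with a size of at least 0.0986, while libraries of 1 group differed by up to 0.272. That call was lost without shCTR 1, shCTR 3 or shC8 2 (adjusted p between 0.127 and 0.276), with the column number range as a term (0.216) and without genes that hold GGACAAA (0.117).

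Some replication-dependent histone genes rose. HIST2H2BF rose by 0.66, HIST1H1E by 0.52, HIST1H2AB by 0.49 and HIST1H1C by 0.44 on the log2 scale. Of 25 tested genes, 7 rose and none fell, with 9 rises adjusted over the list alone (camera adjusted p = 0.00354, adjusted p = 0.826 with an estimated correlation). The median was 0.23, and 0.36 and 0.15 within the lower and upper ranges of column numbers, and at least 0.128 in each of the 3 pairs, while libraries of 1 group differed by up to 0.228. HIST2H2AC, the most abundant, had a change of -0.06 and HIST1H2BC 0.08, neither past the test, and HIST1H2BD rose by 0.43. These genes resemble each other and could share reads. Leaving out 1 library ended the calls of HIST2H2BF (shCTR 1, shCTR 3 or shC8 3, adjusted p up to 0.0712), HIST1H1E (shC8 3, 0.0519), and HIST1H1C and HIST1H2BD (any library except shCTR 2, up to 0.116 and 0.125). With the column number range as a term the adjusted p of HIST1H1C was 0.073 and that of HIST1H2BD 0.0738. Other cell cycle genes showed few calls. Of 38 G2/M genes, TOP2A rose (none with median-of-ratios scaling) and none passed adjusted over the list alone, while 5 rose with the replicate block (camera adjusted p = 0.221). Of 41 DNA replication genes, RFC3 and RFC4 fell and none passed adjusted over the list alone, while 2 rose and 3 fell with the replicate block (camera adjusted p = 0.19), and RFC3 holds GGACAAA.

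Of 30 hypoxia targets, P4HA2 and EGLN3 rose, with 1 rise adjusted over the list alone and 10 with the replicate block, and the camera adjusted p was 0.272, or 0.0229 with the replicate block (adjusted p = 0.76 with an estimated correlation). The hypoxia median was 0.233, but -0.00415, 0.289 and 0.435 in pairs 1, 2 and 3. Within the lower and upper ranges it was 0.0693 and 0.0945. P4HA2 kept its call in 3 and EGLN3 in 1 of the 6 fits without 1 library. No glycolysis gene of 20 passed in limma, over all genes or adjusted over the list alone, but 9 rose with the replicate block, and the camera adjusted p was 0.272, or 0.0229 with the block (adjusted p = 0.76 with an estimated correlation). Of 23 NRF2 targets, AKR1C3 alone rose, over all genes and adjusted over the list alone, while 8 fell with the replicate block, and the camera adjusted p was 0.221, or 0.0189 with the block (adjusted p = 0.76 with an estimated correlation). Their median was 0.03 within the lower and -0.09 within the upper range of column numbers, and 1 of them fell under each scaling, with 0 rises under quantile normalization. Of 73 ribosomal protein genes, RPL4 alone fell, none passed adjusted over the list alone and 8 fell with the replicate block, and the camera adjusted p was 0.0752, or 0.0146 with the block (adjusted p = 0.76 with an estimated correlation). The median of the ribosomal proteins was 0.11 within the lower and -0.08 within the upper range. Of 46 nuclear oxidative phosphorylation genes, 3 rose (NDUFA2, NDUFA4 and UQCR10), with 1 adjusted over the list alone and 6 rises and 3 falls with the block (camera adjusted p = 0.781). Under quantile normalization 4 of these rose and 1 fell, and under median-of-ratios scaling 2 rose and 3 fell. In the autophagy and lysosome list of 26, 5 rose (LAMP1, LAMP2, CTSA and ULK1 among them) and NPC1 fell, with the same counts adjusted over the list alone and 9 and 4 with the block (camera adjusted p = 0.272). The 3' UTR of NPC1 holds GGACAAA, and under median-of-ratios scaling 2 genes of this list rose and 1 fell. The counts of rises and falls were 1 (PDIA4) and 0 of 20 for the unfolded protein response, 1 (SLC38A2) and 1 (VLDLR) of 30 for ATF4 targets and 1 and 1 (EBP) of 23 for cholesterol synthesis. Adjusted over the list alone they were 2 and 1, 1 and 1, and 1 and 1, and with the block 5 and 1, 4 and 5, and 6 and 2. Under median-of-ratios scaling they were 0 and 1, 1 and 3, and 1 and 1, and under quantile normalization 1 and 1 for each. Camera adjusted p values were 0.469, 0.242 and 0.65 for these 3 lists. Both VLDLR and EBP hold GGACAAA. No member of the fatty acid synthesis list (13 tested) or the drug efflux list (11 tested) passed in limma, over all genes or adjusted over the list alone, with 2 rises and 4 falls and 1 rise with the block (camera adjusted p = 0.331 and 0.622).

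Most markers of other cell types were under the level that was tested. Of 12 endothelial markers only KDR was tested, at 1.66 ± 0.298 FPKM in shCTR and 0.986 ± 0.271 in shC8 (SD, n = 3 each), with an adjusted p of 0.0853 by limma, 0.0199 with the replicate block and 0.0496 without shC8 1. The 4 tested immune markers included CD68, at 153 ± 4.19 and 143 ± 7.94 FPKM, with a change of -0.10 that did not pass. LCP1 and FCER1G had changes of 0.31 and -0.69, with adjusted p of 0.414 and 0.054 by limma and of 0.0363 and 0.0347 with the block, and 1 immune marker fell adjusted over the list alone. With median-of-ratios scaling FCER1G passed (adjusted p = 0.0493). Among 5 neuronal markers none passed in limma and 1 rose adjusted over the list alone (camera adjusted p = 0.99), with SNAP25 at -0.18, GAP43 at 0.19 and GAD1 at 0.13. All 3 tested astrocyte and oligodendrocyte markers passed, over all genes and adjusted over the list alone: GJA1 rose by 0.70, CNP by 0.31 and SLC1A3 fell by 0.94. GJA1 lost its call without shCTR 1, shCTR 3, shC8 2 or shC8 3 (adjusted p up to 0.102), and CNP lost it without any 1 library (up to 0.116), with the column number range as a term (0.0637) and with median-of-ratios scaling (0.0567). Of 10 fibroblast and pericyte markers, 4 rose (COL1A1, THY1, CSPG4 and PDGFRB) and none fell, with the same counts adjusted over the list alone and 1 fall with the block (camera adjusted p = 0.308). MCAM had a change of 0.04 and PDPN of -0.61, with an adjusted p of 0.118 for PDPN, 0.00759 with the block and 0.0416 without shCTR 3. The list of small noncoding RNAs of ribosome-depleted libraries had 9 tested genes (camera adjusted p = 0.331). Of these GAS5 alone fell, over all genes and adjusted over the list alone, and it is a long noncoding RNA. RMRP stood at 13400 ± 1690 and 14830 ± 1220 FPKM, RPPH1 at 8371 ± 2390 and 9423 ± 1960 and SCARNA7 at 1912 ± 228 and 1823 ± 199 (SD, n = 3 each), and none of these passed. Mitochondrially encoded genes were absent from the table.

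With the preset correlation, camera called 8 of the 37 lists tested, 3 up and 5 down. With an estimated correlation none was called after adjustment and 1, the MAPK list, had an unadjusted p under 0.05 (0.0182). By fry in 1 direction none was called and 8 had an unadjusted p under 0.05, while fry's mixed test, which asks whether members change either way, called 30. The camera count was 13 with the replicate block, 13 without shCTR 2 and 13 without shC8 1. In 6 lists (angiogenesis, BCL2 family, SRC family, matrix proteases, YAP targets and cholesterol synthesis) the median, the mean and the direction of the camera test were not all of 1 sign.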

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

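The column number term and the fit without genes that hold GGACAAA were chosen after seeing the data. CASP8 stayed lower and past the threshold in all 15 alternatives, between -1.68 and -1.48. The number of genes called was 1401, 3086 with the replicate block, 96 with a log2 threshold of 1, and between 477 and 1346 with 1 library left out. All other settings gave counts within 1.5 times. The number of lists called was 8, 13 with the replicate block, 0 by camera with an estimated correlation, 0 by fry, and between 7 and 13 with 1 library left out. Of 54 called genes named by the rule, 30 kept their call in every alternative and none changed sign. Leaving out 1 library ended the call of 24, and using no filter on low values ended that of 20. Among the genes named by the rule and the lists, the replicate block changed the calls of IL6, KDR, LCP1, FCER1G and PDPN and of 5 lists. With a pseudocount of 0.1, SOX4 was at 1.39, PGF at 1.46, CALCB at 4.03 and UCA1 at 4.66. Of 137 called list members, 44 kept their call in all 6 fits without 1 library and all 137 kept their sign. Calls of the p53 list also ended with a minimum mean of 5 FPKM (adjusted p = 0.12) and with quantile normalization (0.0668), and those of HIST1H1C, HIST1H2BD and CNP with median-of-ratios scaling (0.0628, 0.0653 and 0.0567). HIST1H1C and HIST1H2BD also lost theirs with moderation without a trend (0.0528 and 0.0517) and without genes that hold GGACAAA (0.0524 and 0.0549). Without the filter the proneural list, with more members at low values, was not called (adjusted p = 0.338).

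Signs changed only for genes that did not pass. RELA was at -0.0133 with quantile normalization, -0.0483 with median-of-ratios scaling, -0.0499 with the column number term and between -0.047 and 0.0625 with 1 library left out. SRC was at -0.015 with quantile normalization and MCAM at -0.0106 with median-of-ratios scaling. With 1 library left out, MCAM lay between -0.00942 and 0.0932, RPPH1 between -0.0715 and 0.38, SCARNA7 between -0.166 and 0.0251 and HIST2H2AC between -0.166 and 0.121. The causes were not tested. The depth is unknown. Simulated changes of 0.5 on the log2 scale were recovered for 54% of genes, so smaller changes can be missed. The simulation changed 200 genes and made 146 calls, against 1401 here, so the share recovered in these data can differ.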

Other observations

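The tests of the column number range, of seed matches within the NF-kB and cytokine lists, of another gene lost through the seed, and both tests of TGGTGCT were chosen after the results were seen, as were the gene families described here.

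Beta protocadherin genes, most of which encode neuronal adhesion proteins, come from 1 cluster and mostly rose in shC8. PCDHB17, a pseudogene, is counted among them. Of 13 tested, 12 rose (limma, adjusted p under 0.05), with a median log2 change of 0.71, and 13 rose with the replicate block. PCDHB14 went from 2.33 ± 0.0815 to 5.17 ± 0.599 FPKM and PCDHB10 from 1.49 ± 0.119 to 3.59 ± 0.175 FPKM (SD, n = 3 each). The member that did not pass was PCDHB6, at 0.34 (adjusted p = 0.0606). With quantile normalization and with median-of-ratios scaling, 12 rose each time. Of 8 gamma protocadherins, PCDHGB1 alone rose, by 0.38, and it did not pass under either scaling. These genes resemble each other and share reads to an unknown extent.

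Another ligand gene of the epidermal growth factor receptor fell besides EREG. TGFA, the transforming growth factor alpha gene, fell by 1.19 on the log2 scale (limma adjusted p = 0.00173), and HBEGF had a change of -0.61 (adjusted p = 0.0636, or 0.0171 with the replicate block). Of 6 tested interleukin-1 family genes, IL1B and the receptor antagonist gene IL1RN fell and IL18 rose, and 5 fell with the replicate block. Under quantile normalization and under median-of-ratios scaling 3 of them fell and IL18 did not pass.

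The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As many genes as the real split's 1401 were called in 1 of the 10 splits, the real one, and the highest of the others called 2. The other splits mix shCTR and shC8 libraries, so any real difference between the groups adds to their spread and lowers their counts. Their counts therefore do not give the number that chance alone would call. With the replicate block the real split called 3086, and the other splits that part all 3 pairs called 0 with the block and 0 without it.

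The 1289 genes whose 3' UTR holds GGACAAA had a median log2 change of -0.04, against 0.05 for other genes, and 1046 of them were not called and 58 rose. Of 16170 words, it had the lowest z (-12.55, lowest of 100 reassignments -4.94), it occurs in the coding part of exon 7 of CASP8 (chromosome 2, 201276832 to 201276838), and 185 of 548 fallen genes searched hold it. The z of -12.55 is after adjustment for 3' UTR length and GC content, which argues against these as the whole cause. Silencing of other genes through the hairpin's seed may account for these falls, such as that of TMX3 from 47.7 ± 2.67 to 12.7 ± 0.549 FPKM (SD, n = 3 each). A chance match is not rare, since 20.9% of words occur in CASP8 mRNA, and the hairpin sequence was not available to compare.

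The fall of NF-kB target and cytokine genes was set against the same explanation. With the column number range as a term, 10 genes of the 2 lists were called lower, against 11 without it. IL6, with a limma adjusted p of 0.00799 with the term and 0.0748 without it, was newly called. The count of 10 can hold such genes, so it does not give how many of the 11 kept their call. IL1B, CSF3, IL8, CXCL2 and LIF kept theirs. The median change of the 44 tested list genes was -0.164 within the lower and -0.495 within the upper range. Both medians were negative where the range is constant, but each rests on 1 library of a group (shC8 1 or shCTR 2). So neither the medians nor the count decide whether the range is the whole cause. Of the 11 fallen members, 8 lack even the 6-base core GGACAA in their 3' UTR and 1, CFLAR, holds the full word, which argues against seed matches in their own 3' UTRs. Loss of some other gene through the seed could still lower them, since 185 fallen genes hold the word and the samples carry 1 silencing label, shC8. Loss of Caspase-8 itself also stays open, as untested.

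Genes whose 3' UTR holds TGGTGCT had a median log2 change of 0.07, against 0.03 for other genes. Of all words it had the highest z (5.74, highest of 100 reassignments 5.31), but in pair 1 alone its z was 4.17 and its rank 3. Without 86 genes of the matrix lists its z was 5.09, which is under the highest of the reassignments. The lists need not hold every matrix gene, so the test does not decide whether matrix genes are the whole cause. Both words GGTGCTA (z 5.24) and TGGTGCT match the site of the microRNA miR-29, but they share 6 bases, so the z of GGTGCTA is not separate evidence for lower activity of miR-29. Mature microRNAs were not measured, and miR-29, a change in transcription of these genes and Caspase-8 loss stay open.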
